A study of Glycine max with 12 samples.

How the data were processed

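Total RNA of soybean roots was extracted with TRIzol and sequenced on an Illumina NovaSeq instrument, per the labels, in 12 libraries: 3 each of control, Cd, control+OP and Cd+OP. The deposited table gives 49128 genes of 20 chromosomes with FPKM values and with whole-number counts per library. Aligner, counter, genome build and annotation release are not given in the sources used here. The deposited FPKM values and the counts are not independent. For genes above 1000 counts the ratio of count to FPKM was the same between libraries, up to 1 factor per library, within 1% for 100% of genes. The deposited expected counts were not a plain tally of reads: 10000 values were exactly 4, against 5019 at 3 and 3231 at 5, and 5844 were 8, against 4177 at 7 and 3022 at 9, so that an isolated fragment appears to be worth 4 counts. Total counts were 49904227 to 57693211 per library, and intervals from them would cover counting error only. Ribosomal RNA genes held 0.296 to 0.706% of counts.

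Before the data were examined, the comparisons, the named-gene rule, the list themes and most alternatives were chosen. The test was to be limma on log2(FPKM + 1), or edgeR's quasi-likelihood test if the table held raw counts. The table holds whole-number counts that are not a plain tally of reads, so the choice of edgeR was a judgement made after they were seen. EdgeR 4.0.16 in R 4.3.3 was used, with TMM scaling and 1 mean per group over all 12 libraries. Genes with a mean of at least 1 FPKM were tested (30340 of 49128), two-sided, with Benjamini-Hochberg adjustment over these genes and a threshold of 0.05 per comparison. The comparisons were Cd against control, Cd+OP against Cd, control+OP against control, Cd+OP against control+OP and the interaction of Cd and OP. SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.0796 (0.0324 after division of the counts by 4). P-values measure the spread between these libraries alone, and the labels do not say whether libraries of a group came from separate plants. With counts divided by 4, the median chi-square per gene between libraries of a group was 0.575 to 0.675 over 20422 genes. Sampling alone would give 0.455. The mean was 1.345 to 2.4, so some genes differed more. For most genes the libraries thus differed little beyond sampling noise, and small p-values may say little about variation between plants. Libraries of a group correlated at 0.985 to 0.992 across genes.

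Gene lists were tested with camera (limma 3.58.1) on TMM-scaled log2 counts (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over 31 lists. Fry asks whether the members changed at all, and it gave an adjusted p under 0.05 for most lists in every comparison. With most genes called, it does not set a list apart from other genes, so lists are called by camera below. The lists cover metal chelation and transport, iron deficiency, glutathione transferases, sulfur and glutathione synthesis, antioxidant enzymes, class III peroxidases, oxidative burst, heat shock, ABC and MATE transporters, cytochrome P450, isoflavonoids, lignin, endodermis and suberin, wall expansion, ethylene, auxin, jasmonate, abscisic acid and dehydration, defense proteins, protease inhibitors, nodulation, nitrogen, phosphate, aquaporins, cell division, ribosomal proteins, photosynthesis, seed storage, xylem and phloem, and senescence and proteolysis. The table describes 47876 genes (97.5%) as hypothetical proteins, 105 of 48401 protein-coding genes have a symbol, and 0 identifiers matched the reference table of gene names. The members were therefore set by Gene Ontology and KEGG terms (39744 genes have one) and symbols, chosen after the annotation columns were seen and before any test, and lists for WRKY and NAC factors were not built. Members are as broad as their terms: the nodulation list holds every oxygen carrier, and the jasmonate list every oxylipin gene. In addition 1835 annotation terms of 10 to 500 tested genes were tested with camera.

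Genes named are, per comparison, among the 6 highest and 6 lowest log2 fold changes of called genes with a mean of at least 5 FPKM, groups that do not overlap (not asked of the interaction) and an annotation, or among the 3 members of a list with the smallest adjusted p. An annotation was taken as a symbol, a KEGG term or a specific Gene Ontology term. Of 297 such genes 97 are named, others being left out for length.

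On simulated counts with the dispersion of the data (5 simulations of Cd against control, written after the first results had been seen), edgeR recovered 31.2, 74, 92 and 100% of genes changed 1.2-, 1.5-, 2- and 4-fold, and 69 of 901 calls (7.7%) were false, above the nominal share. Camera called the changed list in 5 of 5 simulations and 0 of 150 random lists. Genes were simulated independently of each other, with 200 genes and a list of 60 changed per simulation. Lists of correlated genes and changes in most genes, as in the data, were therefore not covered. The alternatives were a pseudocount of 0.1 on FPKM with limma, no filter, a mean of at least 5 FPKM, median of ratios scaling, array weights, the replicate number as a block, a 2-fold minimum, the compared groups alone, an estimated correlation within lists, and each library left out in turn. Limma on log2(FPKM + 1), the test first planned for FPKM values, became an alternative after the data were seen. DESeq2 1.42.0, counts divided by 4 and all alternatives for annotation terms were added then too.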

Results

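Root RNA of soybean (Glycine max, cultivar Williams 82) was sequenced in 12 libraries from 4 groups of 3: control, cadmium (Cd), control with OP (control+OP) and cadmium with OP (Cd+OP). OP stands for Oceanobacillus picturae, a bacterium named in the series title, which is about Cd stress and the growth of soybean seedlings. The dose label, 70 mg/L Cd, stands on every sample including the controls, so it could not be tied to a group, and plant age, exposure time and inoculation are not given in the sources used here. Total counts were 57693211, 52799722 and 49904227 in the control libraries and 52862699, 52134974 and 51768348 with Cd. They were 51179042, 52426250 and 50366888 in control+OP and 50444683, 53797363 and 52866221 in Cd+OP. Counts above 0 were found for 42224 to 43313 of 49128 genes per library, and 30340 genes with a mean of at least 1 FPKM (fragments per kilobase, scaled to library size) were tested. In 107 of 107 results named below for 2 groups, the libraries of the groups did not overlap. This follows largely from the choice of the genes, which asked for it or for the smallest adjusted p on a list, so it is no separate support. The 10% that chance gives holds only for genes not chosen in this way. Levels below are mean FPKM ± SD of the 3 libraries of a group, and changes are log2 fold changes ± SE of the edgeR fit with n = 3 per group. That SE is derived from the F statistic. For genes with a group near 0 FPKM, where the SD is nearly as large as the mean, it can understate the spread between libraries. Gene positions are those of the deposited table, whose genome build is not given in the sources used here.

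The Cd libraries lay apart from the other groups. On the first principal component, which held 65.6% of the variance, the Cd libraries stood at 138.13 to 153.71 and the other 9 libraries at -98.08 to -16.15. Across genes, mean correlations between libraries were 0.942 for Cd+OP and control, 0.91 for control+OP and control, 0.877 for Cd+OP and Cd, and 0.846 for Cd and control (genes are not independent replicates). Within groups they were 0.985 to 0.992.

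**Figure D1:**
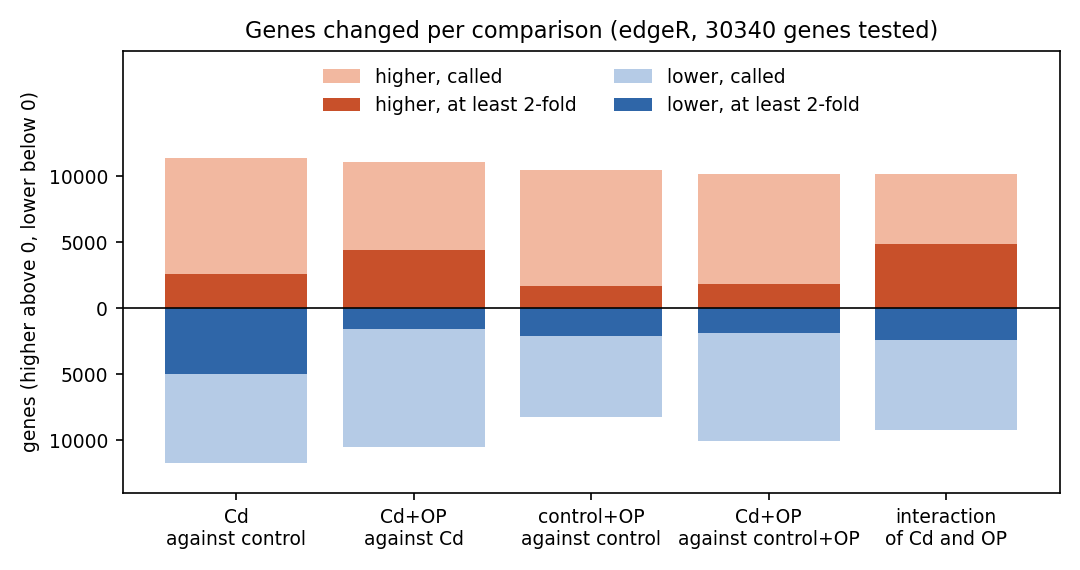
Genes changed in each comparison, as the number called higher (above 0) or lower (below 0) by edgeR, with the part that changed at least 2-fold in dark colour. Cd against control had the largest count of the 5, 23132 genes, with 4962 at least 2-fold lower and 2608 at least 2-fold higher.

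Cd against control asks how roots with the metal alone differ from control roots, with growth conditions per group not given in the sources used here. Some genes annotated with fatty acid binding and systemic acquired resistance were among those with the largest rises, with GLYMA_11G225000 (chromosome 11, 31994088 to 31994683) going from 29.9 ± 3.24 to 2749 ± 126 FPKM (log2 6.53 ± 0.0665, adjusted p = 2.50e-29, edgeR). GLYMA_18G033100 and GLYMA_18G032600 rose by 6.45 and 6.36 on the log2 scale. Some protease inhibitor genes, whose products block protein digestion, rose too. GLYMA_09G163200 (chromosome 9, 38784214 to 38785079) went from 4.81 ± 1.0 to 433 ± 2.61 FPKM (log2 6.49 ± 0.0721), and its neighbours GLYMA_09G162800 and GLYMA_09G163800 rose by 5.73 and 3.97. At the other end GLYMA_06G088800 (chromosome 6, 6878707 to 6881320), a protein kinase gene annotated with mitotic spindle organization, fell from 9.55 ± 0.415 to 0.0955 ± 0.084 FPKM (log2 -6.58 ± 0.242, adjusted p = 4.35e-18, edgeR). How far relatives such as those on chromosome 9 share reads could not be seen from the table, so their separate values are uncertain.

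Water channel genes (aquaporins, which let water cross membranes) were lower with Cd: 31 of 35 tested members fell and 3 rose, with a median log2 change of -1.73 (camera adjusted p = 4.93e-12). GLYMA_05G208700 fell from 54.6 ± 0.55 to 4.11 ± 0.142 FPKM, and the abundant GLYMA_13G325900 from 390.2 ± 8.13 to 93. ± 4.32 FPKM (log2 -3.73 ± 0.0592 and -2.07 ± 0.0375). Cell division genes fell in 247 of 369 members and rose in 69 (median -0.68, camera adjusted p = 1.13e-08). Among those that fell were the cyclin-type regulators GLYMA_02G277600 (log2 -4.57 ± 0.116) and GLYMA_08G291000 (log2 -2.25 ± 0.058) and the tubulin-type gene GLYMA_04G088500 (log2 -2.13 ± 0.0555). Xylem and phloem genes fell in 65 of 92 members and rose in 17 (median -2.18, camera adjusted p = 7.85e-07). GLYMA_02G000700, annotated with phloem development, fell from 39.7 ± 0.694 to 2.49 ± 0.341 FPKM, and GLYMA_10G000500 and GLYMA_10G185700 of the same annotation changed by -3.27 and -4.87. Endodermis and suberin genes, which build the root's inner barrier, fell in 23 of 28 members and rose in 1 (median -2.12, camera adjusted p = 1.06e-04). The Casparian strip gene GLYMA_10G075500 stood at 3.3 ± 0.714 and 0.0815 ± 0.0711 FPKM. Photosynthesis genes, a marker list for green tissue, fell in 47 of 89 members and rose in 18 (camera adjusted p = 0.00432). GLYMA_19G046800, annotated with ribulose-bisphosphate carboxylase, went from 15.4 ± 2.29 to 0.40 ± 0.0917 FPKM.

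Jasmonate genes fell in 81 of 125 members and rose in 29 (median -0.59, camera adjusted p = 2.11e-06), though adjusted p = 0.0631 with an estimated correlation. The lipoxygenase gene LOX1.4 (GLYMA_07G007000), which is on the list by name but carries the enzyme code of a lipoxygenase type outside jasmonate synthesis, fell from 827 ± 29.6 to 67.1 ± 0.59 FPKM (log2 -3.62 ± 0.0295, adjusted p = 6.01e-31, edgeR). The related GLYMA_13G347700 and GLYMA_07G034800 changed by -3.74 and -5.42. Ribosomal protein genes fell in 386 of 583 members and rose in 72 (median -0.32, camera adjusted p = 1.43e-06), with GLYMA_10G223400 at log2 -0.93 ± 0.0305 and adjusted p = 0.0731 with an estimated correlation. Lignin genes fell in 20 of 27 members (median -2.23, camera adjusted p = 0.00234), and adjusted p = 0.0631 with an estimated correlation. Wall expansion genes fell in 139 of 243 and defense protein genes in 48 of 83 (camera adjusted p = 0.0075 and 0.0159), and adjusted p = 0.0754 and 0.112 with an estimated correlation. Seed storage genes, the marker list for seed remnants, fell in 32 of 59 members and oxidative burst genes in 12 of 16 (camera adjusted p = 0.0075 and 0.0193), and adjusted p = 0.112 and 0.0691 with an estimated correlation. Class III peroxidase genes fell in 63 of 114 members and rose in 43, with GLYMA_05G103600 and GLYMA_03G208200 at log2 -3.40 and -5.63 (camera adjusted p = 0.0449), and adjusted p = 0.138 with an estimated correlation.

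Protease inhibitor genes as a list rose in 32 of 51 members and fell in 15, among the latter GLYMA_18G231400 (log2 -5.70 ± 0.213), with a median of 0.68 (camera adjusted p = 0.0023). Metal transport genes rose in 51 of 102 members and fell in 21 (median 0.28, camera adjusted p = 0.0161). Among them were GLYMA_08G181900 (chromosome 8, 14599603 to 14600656), annotated with iron and manganese transport, at 5.42 ± 0.433 and 52.4 ± 3.33 FPKM (log2 3.27 ± 0.0821), and the copper pump gene GLYMA_01G219000 (log2 0.78 ± 0.0324). Senescence and proteolysis genes rose in 90 of 177 members and fell in 33 (median 0.17, camera adjusted p = 0.00468), with the macroautophagy gene GLYMA_17G084700 at log2 1.45 ± 0.061. Isoflavonoid genes rose in 46 of 88 and fell in 34 (camera adjusted p = 0.0134), and adjusted p = 0.0754 with an estimated correlation. The chalcone synthase-type gene GLYMA_11G011500 rose by 1.79, whereas CYP93E1 (GLYMA_08G350800), on that list by its name but known for triterpenoid synthesis, changed by -4.21. The abscisic acid and dehydration list did not pass (68 members higher, 89 lower, camera adjusted p = 0.421), although its abscisic acid binding members GLYMA_09G040400 and GLYMA_15G145600 rose by 5.55 and 4.73. The numbers of members higher and lower on the other lists were 67 and 56 for ABC and MATE transporters, 94 and 154 for auxin, 67 and 80 for cytochrome P450, 21 and 37 for iron deficiency. They were 7 and 15 for metal chelation, 28 and 37 for nitrogen, 18 and 38 for phosphate, and 23 and 36 for sulfur and glutathione synthesis. Further numbers were 17 and 31 for antioxidant enzymes, 49 and 63 for ethylene, 24 and 30 for glutathione transferases (median 0.01, mean -0.18), 115 and 104 for heat shock, and 8 and 11 for nodulation. None of these 13 lists passed with camera in this comparison, with camera adjusted p from 0.0645 to 0.824. Fry, which does not compare a list with other genes, passed every list here, with fry adjusted p of at most 0.00141.

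In edgeR 23132 of 30340 genes were called for Cd against control, 11402 higher and 11730 lower. Of 31 lists camera called 17, 4 higher and 13 lower, of which 8 held with an estimated correlation (aquaporins, cell division, xylem and phloem, endodermis and suberin, photosynthesis, protease inhibitors, metal transport, senescence and proteolysis). Adjusted over the list alone, 31 aquaporin genes, 247 cell division genes and 66 xylem and phloem genes fell and 32 protease inhibitor genes rose. Of 1835 annotation terms 327 passed, and 0 with an estimated correlation, where 434 had an unadjusted p under 0.05. With genes of at least 5 FPKM, only 6 endodermis and suberin members and 9 lignin members stayed and both calls ended, the latter with a median of 0.26, as did the calls for wall expansion, defense proteins, oxidative burst, metal transport and class III peroxidases. With no filter the isoflavonoid and seed storage calls ended. The class III peroxidase call also ended with DESeq2, with limma, with median of ratios scaling, and without control library 1, 2 or 3, Cd library 1 or 2 or control+OP library 1, 2 or 3 (camera adjusted p = 0.0514 to 0.0734 without 1 of these 8, and 0.0287 to 0.119 over all alternatives).

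**Figure D2:**
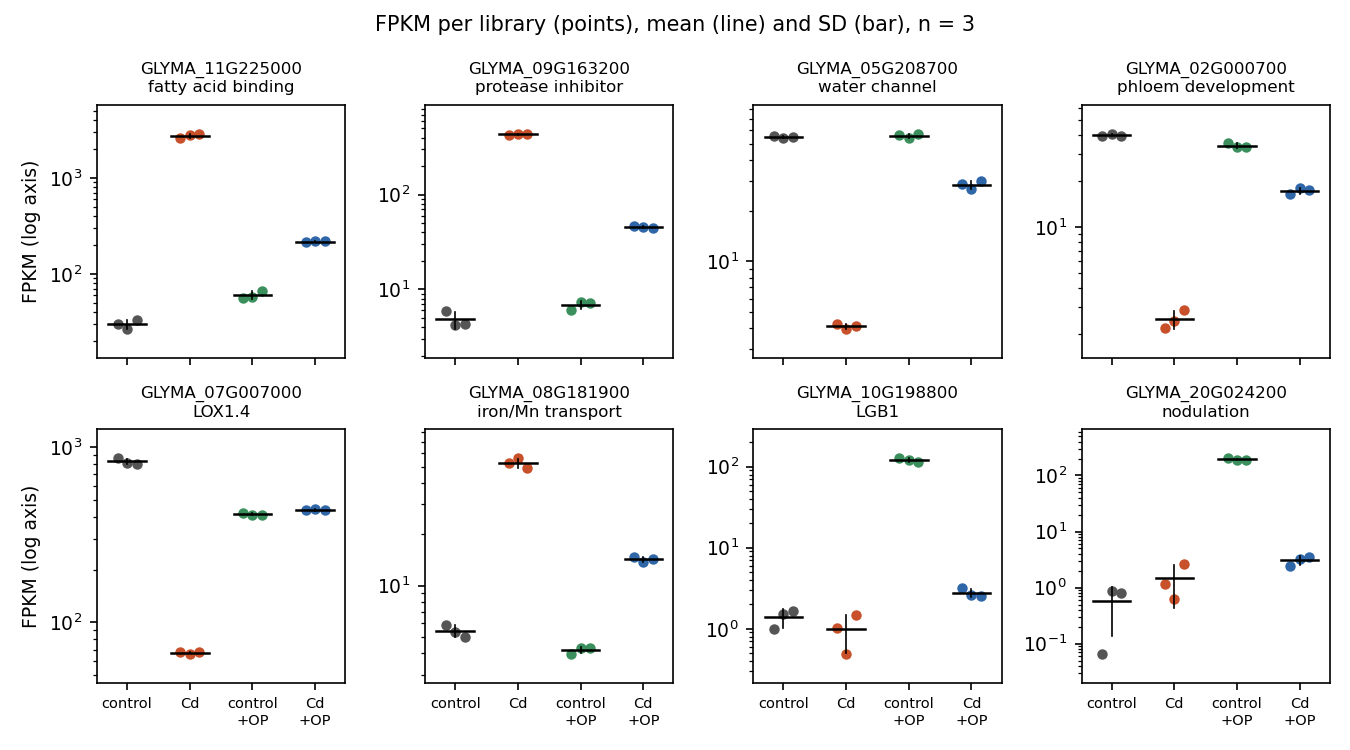
Levels of 8 named genes in each library, in FPKM on a log axis, with the 3 libraries of a group as points, their mean as a line and their SD as a bar. GLYMA_11G225000 had means of 29.9, 2749, 59.8 and 217 FPKM in control, Cd, control+OP and Cd+OP, and LGB1 had 1.4, 0.999, 121 and 2.78 FPKM.

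Cd+OP against Cd asks what the bacterium changes in roots under Cd. Some genes that Cd had raised were far lower with OP: the protease inhibitor gene GLYMA_09G162800 went from 487 ± 16.6 to 23.2 ± 0.643 FPKM (log2 -4.46 ± 0.0588, adjusted p = 1.07e-26, edgeR). Its neighbours GLYMA_09G162500 and GLYMA_09G163000 stood at log2 -4.53 and -4.50, and the fatty acid binding gene GLYMA_18G032400 went from 1522 ± 20.6 to 73.8 ± 0.252 FPKM (log2 -4.44 ± 0.057). GLYMA_05G065700, annotated as extracellular, changed by -4.44. The spindle kinase gene GLYMA_06G088800 rose from 0.0955 ± 0.084 to 7.53 ± 0.574 FPKM (log2 6.17 ± 0.247). VSPB (GLYMA_08G200100), a vegetative storage protein, rose from 2.55 ± 2.09 to 125 ± 1.95 FPKM (log2 5.54 ± 0.204), above its control level of 20.3 ± 1.75 FPKM. The methyltransferase gene GLYMA_16G134600, the transcription factor genes GLYMA_10G067000 and GLYMA_03G002300 and the vesicle fusion gene GLYMA_02G069700 rose by 6.38, 5.51, 5.36 and 5.09.

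Jasmonate genes rose in 80 of 125 members and fell in 25 (median 0.72, camera adjusted p = 2.50e-09). LOX1.4 went from 67.1 ± 0.59 to 438 ± 4.13 FPKM, with the jasmonate synthesis gene GLYMA_14G078600 at log2 2.83 ± 0.0377. Aquaporin genes rose in 26 of 35 members and fell in 6 (median 1.06, camera adjusted p = 2.58e-07). GLYMA_05G208700 reached 28.5 ± 1.49 FPKM against 54.6 ± 0.55 in control, and GLYMA_11G228000 rose from 17.4 ± 0.498 to 77.5 ± 2.32 FPKM. Cell division genes rose in 234 of 369 members and fell in 72 (median 0.59, camera adjusted p = 4.53e-07), with the cyclin-type genes GLYMA_02G277600 and GLYMA_14G037100 at log2 4.22 ± 0.117 and 4.52 ± 0.13. Xylem and phloem genes rose in 61 of 92 and fell in 18 (median 1.78, camera adjusted p = 2.37e-05). Endodermis and suberin genes rose in 22 of 28 and fell in 3 (median 1.96, camera adjusted p = 8.83e-05). Examples were GLYMA_02G000700 at 17.2 ± 0.75 FPKM and GLYMA_14G192500, a monooxygenase gene on the suberin list, at log2 3.01 ± 0.17. Seed storage genes rose in 37 of 59 members and fell in 9 (median 0.91, camera adjusted p = 1.94e-05). GLYMA_16G060800, annotated as a nutrient reservoir protein of the cell wall and vacuole, stood at 51.5 ± 1.28 and 168 ± 0.896 FPKM.

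Protease inhibitor genes fell in 30 of 51 members and rose in 14 (camera adjusted p = 3.33e-04). Senescence and proteolysis genes fell in 87 of 177 and rose in 38 (camera adjusted p = 0.00612), and metal transport genes fell in 49 of 102 and rose in 21 (camera adjusted p = 0.0284). GLYMA_17G084700 changed by -1.18 and GLYMA_08G181900 by -1.95, to 14.3 ± 0.427 FPKM. Ribosomal protein genes rose in 379 of 583 members (camera adjusted p = 4.53e-07), GLYMA_10G223400 among them (log2 0.71 ± 0.0305), and adjusted p = 0.0807 with an estimated correlation. Lignin genes rose in 18 of 27 (camera adjusted p = 0.0128) and class III peroxidase genes in 60 of 114 (camera adjusted p = 0.0229), and adjusted p = 0.101 and 0.127 with an estimated correlation. Isoflavonoid genes fell in 45 of 88 and rose in 29 (camera adjusted p = 0.0153), with CYP73A11 (GLYMA_02G236500), a cinnamate hydroxylase of the phenylpropanoid pathway, from 386 ± 9.68 to 94.6 ± 3.67 FPKM, and adjusted p = 0.0989 with an estimated correlation.

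For Cd+OP against Cd edgeR called 21553 genes, 11055 higher (51.3%, and 57.2 to 57.5% with limma) and 10498 lower, 4410 and 1580 of them at least 2-fold. Camera called 13 of 31 lists, 9 with an estimated correlation, and 291 of 1835 annotation terms, 15 with an estimated correlation. Adjusted over the list alone, 80 jasmonate, 26 aquaporin and 236 cell division genes rose and 30 protease inhibitor genes fell. With genes of at least 5 FPKM, the calls for endodermis and suberin (6 members, median -0.05), lignin (9 members, median -0.38) and metal transport ended. The isoflavonoid call ended with no filter and the class III peroxidase call with limma on log2 FPKM with either pseudocount.

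Control+OP against control asks what the bacterium does without Cd. The nodulation gene GLYMA_20G024200 (chromosome 20, 2636776 to 2638588) rose from 0.585 ± 0.45 to 193 ± 7.33 FPKM (log2 8.37 ± 0.241, adjusted p = 4.86e-20, edgeR), and GLYMA_13G364400, GLYMA_15G045000, GLYMA_14G052400 and GLYMA_08G120100 of the same list rose by 7.75, 7.82, 7.69 and 7.74. The leghaemoglobin genes LGB1 (GLYMA_10G198800, chromosome 10, 42995962 to 42997094) and LBA (GLYMA_10G199100), whose products carry oxygen in root nodules, went from 1.4 ± 0.365 and 0.164 ± 0.142 to 121 ± 5.46 and 33.3 ± 0.363 FPKM (log2 6.44 ± 0.159 and 7.62 ± 0.285). Alcohol dehydrogenase gene GLYMA_04G213900 (chromosome 4, 48558152 to 48562318) fell from 259 ± 11.4 to 12.8 ± 0.749 FPKM (log2 -4.33 ± 0.0426), and GLYMA_19G213100, an ethylene pathway regulator annotated with response to anoxia, fell from 283 ± 10.8 to 34. ± 1.43 FPKM.

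Of 28 nodulation list genes 21 rose and 6 fell, with a median of 4.98 (camera adjusted p = 0.00175), and adjusted p = 0.328 with an estimated correlation. Members that fell included the oxygen carrier GLYMA_11G121800, from 647 ± 32.5 to 92.1 ± 7.77 FPKM, and the sucrose synthase gene SS (GLYMA_13G114000), an enzyme of sucrose breakdown, from 472 ± 18.1 to 189 ± 4.41 FPKM (log2 -2.81 ± 0.046 and -1.32 ± 0.0302). Ribosomal protein genes rose in 378 of 583 members (median 0.25, camera adjusted p = 5.77e-09), GLYMA_14G061100 by 0.58, and adjusted p = 0.0974 with an estimated correlation. Isoflavonoid genes rose in 59 of 88 members and fell in 16 (median 0.39, camera adjusted p = 3.99e-04), and adjusted p = 0.0873 with an estimated correlation. The O-methyltransferase gene GLYMA_11G054500 rose from 6.54 ± 0.544 to 94.4 ± 5.11 FPKM and the monooxygenase gene GLYMA_20G114200 changed by -2.70. Wall expansion genes rose in 142 of 243 members and fell in 54, among the latter the pectinesterase genes GLYMA_01G137700 and GLYMA_03G029400, which act on wall pectin, at log2 -1.95 ± 0.0328 and -2.18 ± 0.0439 (camera adjusted p = 0.00286), and adjusted p = 0.109 with an estimated correlation. Heat shock genes rose in 133 of 289 (camera adjusted p = 0.0162), with the chaperone genes GLYMA_03G171100 and GLYMA_12G064000 at log2 1.10 ± 0.0272 and 1.15 ± 0.0301, and adjusted p = 0.109 with an estimated correlation. Cell division genes rose in 188 of 369 members and fell in 67 (median 0.28, camera adjusted p = 0.0284), whereas the chromatin genes GLYMA_17G255600 and GLYMA_10G163300 of that list, which package DNA, changed by -1.09 and -0.97.

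Aquaporin genes fell in 16 of 35 members and rose in 6 (median -0.13, camera adjusted p = 0.00607), with GLYMA_13G325900 and GLYMA_19G108400 at log2 -1.14 ± 0.0363 and -1.48 ± 0.0463, and adjusted p = 0.17 with an estimated correlation. Protease inhibitor genes fell in 28 of 51 members and rose in 17 (camera adjusted p = 0.0166), with GLYMA_16G212200, GLYMA_16G212400 and GLYMA_08G341400 at -4.82, -2.89 and -1.69, and adjusted p = 0.109 with an estimated correlation. The protease gene GLYMA_10G180500, the ADP-ribosyltransferase gene GLYMA_04G183100 and the transporter gene GLYMA_06G192100 also fell, to log2 changes of -4.50, -4.47 and -4.96. The metalloprotease gene GLYMA_02G028600 also fell (log2 -6.81, adjusted p = 0.00607, edgeR), on uneven libraries: it stood at 31.8, 0.116 and 5.03 FPKM in control and at 0.11, 0.11 and 0.086 FPKM in control+OP, and the call ended with limma and without control library 1 (log2 -4.64, adjusted p = 0.0856, edgeR). The chitinase gene GLYMA_02G042500, which digests fungal walls, rose by 3.16, on a defense protein list that did not pass (41 of 83 members higher, 21 lower, camera adjusted p = 0.0651).

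For control+OP against control edgeR called 18761 genes, 10496 higher and 8265 lower, 1667 and 2114 of them at least 2-fold. The share of calls that were higher, 55.9%, fell to 49.9% with the compared groups alone, 49.8% with no filter, 49.3% with genes of at least 5 FPKM and 48.9 to 49.5% without any 1 of the control and Cd libraries, so the excess of rises depended on these settings. Camera called 8 of 31 lists, only cell division with an estimated correlation (adjusted p = 0.0279), and 230 of 1835 annotation terms, 0 with an estimated correlation, where 362 had an unadjusted p under 0.05. Adjusted over the list alone, 21 nodulation and 190 cell division genes rose and 28 protease inhibitor genes fell. With genes of at least 5 FPKM the calls for cell division and protease inhibitors ended, and with no filter that for heat shock.

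Cd+OP against control+OP asks what Cd does in roots that had the bacterium. The nodulation gene GLYMA_20G024200 was far lower with Cd, at 3.07 ± 0.586 FPKM against 193 ± 7.33 (log2 -6.04 ± 0.193, adjusted p = 1.14e-18, edgeR), and so was LGB1 at 2.78 ± 0.322 against 121 ± 5.46 FPKM (log2 -5.51 ± 0.146). GLYMA_13G364400, GLYMA_15G045000, GLYMA_14G052400 and the oxygen carrier GLYMA_10G199000 changed by -6.05, -6.13, -6.22 and -6.03, and the aspartic protease gene GLYMA_15G260700 by -5.92. Among annotated genes with a mean of at least 5 FPKM, large rises were those of GLYMA_01G202100 (extracellular, log2 4.09 ± 0.239), GLYMA_11G158200 (circadian rhythm, 2.70 ± 0.106), GLYMA_04G239900 (ceramide transport, 2.66 ± 0.141), GLYMA_02G008200 (transcription factor, 2.64 ± 0.182), GLYMA_10G201700 (mannan synthase, 2.57 ± 0.0746) and the protease inhibitor gene GLYMA_09G163200 (2.65 ± 0.0694).

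The nodulation list fell in 23 of 28 members and rose in 3 (median -4.37, camera adjusted p = 8.42e-07), and adjusted p = 0.145 with an estimated correlation. Wall expansion genes fell in 171 of 243 members and rose in 45 (median -0.73, camera adjusted p = 1.25e-09), with the cellulose synthase gene GLYMA_06G324300 from 51.6 ± 1.52 to 14.9 ± 0.388 FPKM. Ribosomal protein genes fell in 371 of 583 members (median -0.26, camera adjusted p = 7.41e-10), with GLYMA_10G048600 at log2 -0.83 ± 0.0318. Cell division genes fell in 242 of 369 members (median -0.43, camera adjusted p = 1.60e-07), among them the tubulin-type genes GLYMA_04G023900 and GLYMA_06G024100 with log2 changes of -1.59 and -1.59. Xylem and phloem genes fell in 65 of 92 (median -0.73, camera adjusted p = 1.28e-05) and lignin genes in 21 of 27 (median -0.64, camera adjusted p = 9.71e-04), with the secondary wall gene GLYMA_13G293500 and the laccase-type gene GLYMA_14G056100 at log2 -1.51 ± 0.0649 and -1.73 ± 0.116. Defense protein genes fell in 49 of 83 and rose in 18 (camera adjusted p = 1.27e-04), with the glucanase gene GLYMA_03G132700 from 687 ± 6.91 to 97.6 ± 1.66 FPKM. Photosynthesis genes fell in 44 of 89 (camera adjusted p = 0.0203). Protease inhibitor genes rose in 32 of 51 members and fell in 10 (median 0.67, camera adjusted p = 8.05e-05), with GLYMA_09G163300 at log2 2.44 ± 0.0719. Senescence and proteolysis genes rose in 84 of 177 (camera adjusted p = 0.0435).

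Aquaporin genes fell in 23 of 35 members (median -0.29, camera adjusted p = 0.00135), with GLYMA_03G185900 at 591 ± 18.3 and 304 ± 9.67 FPKM, and adjusted p = 0.119 with an estimated correlation. Glutathione transferase genes, which attach glutathione to reactive compounds, rose in 36 of 69 members and fell in 15, with GLYMA_11G198500 at log2 1.52 ± 0.0618 (camera adjusted p = 0.00285), and adjusted p = 0.154 with an estimated correlation. Antioxidant enzyme genes fell in 33 of 70 and isoflavonoid genes in 46 of 88 (camera adjusted p = 0.0308 and 0.0316), and adjusted p = 0.155 and 0.139 with an estimated correlation. CYP93E1 fell from 147 ± 3.7 to 42.2 ± 3.73 FPKM.

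In this comparison edgeR called 20229 genes, 10183 higher (50.3%, and 57.3 to 57.6% with limma) and 10046 lower, 1828 and 1905 of them at least 2-fold. Camera called 14 of 31 lists and 502 of 1835 annotation terms, and with an estimated correlation 10 lists (9 of these 14 and ethylene, adjusted p = 0.0469, 0.058 with the preset correlation) and 216 terms. Adjusted over the list alone, 23 nodulation and 171 wall expansion genes fell and 33 protease inhibitor genes rose. With genes of at least 5 FPKM the calls for lignin, photosynthesis, senescence and proteolysis and isoflavonoids ended. The antioxidant call ended with limma on log2(FPKM + 1), with equal or array weights, but not with a pseudocount of 0.1, and the senescence call without Cd+OP library 1 (camera adjusted p = 0.0511, and 0.0151 to 0.261 over all alternatives).

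The interaction of Cd and OP, the OP effect under Cd minus the OP effect without Cd, asks whether the bacterium acts differently in the presence of the metal. Of 28 nodulation genes 21 had lower OP effects under Cd and 4 higher (median -3.34, camera adjusted p = 0.00392), and adjusted p = 0.33 with an estimated correlation. GLYMA_20G024200 stood at -7.37 ± 0.473 (adjusted p = 7.47e-13, edgeR) and the oxygen carrier GLYMA_11G121800 at 3.33. The spindle kinase gene GLYMA_06G088800 had a far higher OP effect under Cd, at 5.79 ± 0.30. Aquaporin genes had higher OP effects under Cd in 29 of 35 members (median 1.47, camera adjusted p = 2.34e-09), with GLYMA_13G325900 at 2.18 ± 0.0516. So had jasmonate genes in 79 of 125 (median 0.73, camera adjusted p = 1.52e-08), with LOX1.4 at 3.63 ± 0.0388. Endodermis and suberin genes (median 1.68, 23 of 28 higher, camera adjusted p = 1.90e-04), xylem and phloem genes (1.18, 54 of 92, 0.00202), cell division genes (0.37, 193 of 369, 0.00161) and ethylene genes (0.27, 69 of 135, 0.0376) had higher OP effects under Cd. Isoflavonoid genes had lower ones in 52 of 88 members (median -0.37, camera adjusted p = 1.86e-05), with CYP73A11 at -2.04 ± 0.0492.

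Seed storage genes (35 of 59 higher) and metal chelation genes (17 of 27 higher) passed with camera adjusted p = 0.00339 and 0.0214, and adjusted p = 0.102 and 0.079 with an estimated correlation. GLYMA_18G045200, annotated with response to cadmium ion, stood at 181 ± 10.6, 48. ± 1.45, 103 ± 4.02 and 139 ± 3.08 FPKM in control, Cd, control+OP and Cd+OP (interaction 2.27 ± 0.0526). Heat shock genes (112 of 289 lower) passed with camera adjusted p = 0.0312, and adjusted p = 0.107 with an estimated correlation. The dioxygenase gene GLYMA_10G092800, the aminotransferase gene GLYMA_01G131100, the calcium and phospholipid binding gene GLYMA_13G199500 and the Casparian strip gene GLYMA_10G075600 stood at 5.62 ± 0.234, 5.54 ± 0.118, 5.25 ± 0.186 and 4.01 ± 0.338. EdgeR called 19381 genes for the interaction, 10143 higher and 9238 lower, 4830 and 2373 of them at least 2-fold. Camera called 11 of 31 lists, 7 with an estimated correlation, and 327 of 1835 terms, 14 with an estimated correlation. With genes of at least 5 FPKM the calls for cell division, xylem and phloem, and endodermis and suberin ended, with no filter those for heat shock and seed storage, and with limma on log2 FPKM, with either pseudocount, those for ethylene and heat shock.

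**Figure D3:**
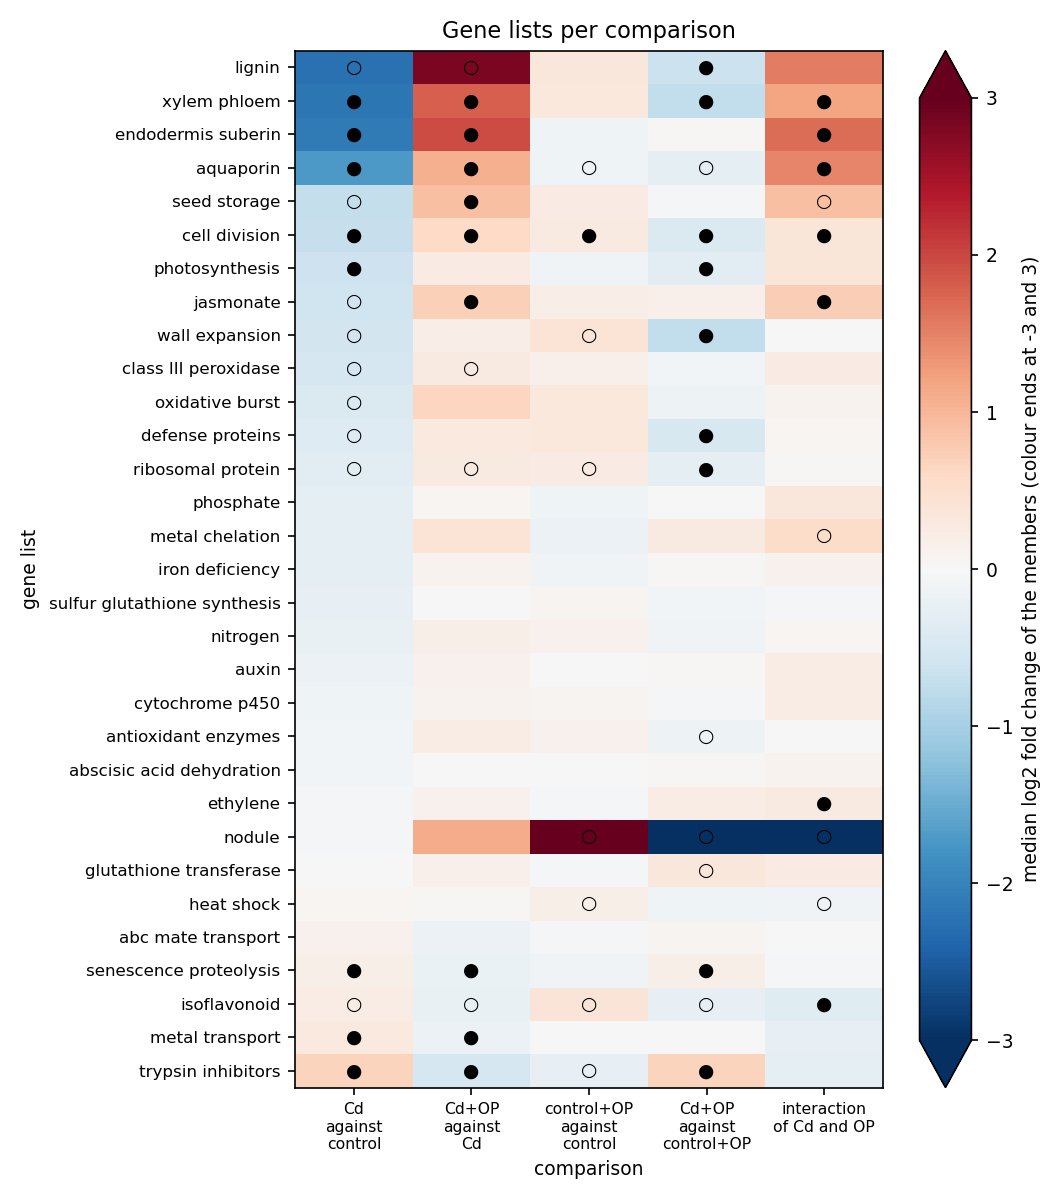
Median log2 fold change of the members of 31 gene lists (vertical axis) in 5 comparisons (horizontal axis), with colour from blue (lower) to red (higher). Open circles mark lists that camera called with the preset correlation alone, and filled circles those it also called with an estimated correlation, 8, 9, 1, 9 and 7 lists from left to right.

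The Cd response was smaller in roots with OP. Across 30340 genes the log2 changes of Cd+OP against control+OP had a slope of 0.25 (jackknife SE 0.0118, and 0.1639 with no filter on low values) on those of Cd against control, with Pearson r = 0.381 and Spearman rho = 0.375. These contrasts share no library, and genes are not independent replicates. The SD of the log2 changes was 1.17 without OP and 0.769 with OP. The slope falls with the correlation as well as with the size of the response, so it does not measure size alone. Genes higher in both numbered 5614, where 3827 were expected from the separate counts, genes lower in both 5832 (expected 3884), and genes called in opposite directions 4783 (expected 7712).

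Of the 23132 genes called for Cd against control, 16441 (71.1%) were called in the opposite direction for Cd+OP against Cd and 1695 (7.3%) in the same direction. Among them 7677 genes were higher with Cd and then lower with OP, where 3945 were expected from the separate counts, and 8764 were lower and then higher, where 4274 were expected. Of the 7570 genes changed at least 2-fold by Cd, 7091 (93.7%) lay closer to control in Cd+OP, with a median of 26.6% of the change remaining, and 1676 were still at least 2-fold from control. In edgeR 14863 (64.3%) of the Cd-called genes still differed between Cd+OP and control, 11611 on the side of the Cd change and 3252 beyond control. Both contrasts use the same Cd libraries, which alone gives opposite signs. In simulated unchanged groups 66.7% of genes had opposite signs against 79.5% observed, r was -0.5 against -0.83, and the covariance was -0.01 against -1.02. The simulation covers the noise of single libraries alone. A shift shared by all Cd libraries, such as a batch, would also give opposite signs and was not simulated.

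**Figure D4:**
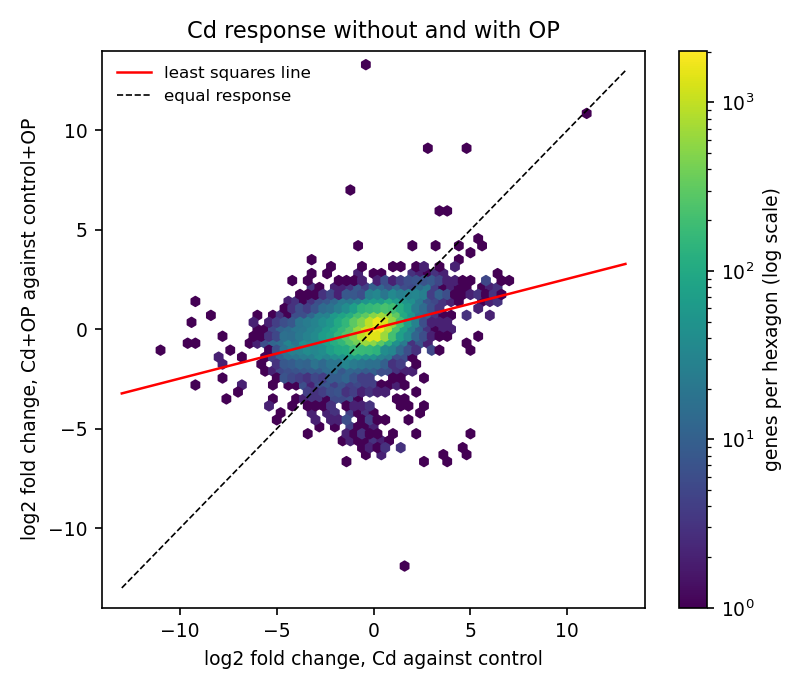
Log2 fold change of each of 30340 genes for Cd against control (horizontal axis) and Cd+OP against control+OP (vertical axis), with colour for the number of genes per hexagon on a log scale, the least squares line in red and equal responses as a dashed line. The line has a slope of 0.25, below the slope of 1 that equal responses would give. A low slope reflects the low correlation of the responses (r = 0.381) as well as their size (SD 1.17 without OP and 0.769 with OP).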

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

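The tests of a mislabelled library, of noise in the Cd contrast, of the genes with the most counts, of vascular cells and of carry-over were chosen only after the result was seen. The OP effect differed with and without Cd for 19381 genes in edgeR. In 100 relabellings of the 12 libraries, the real labels included, the highest other count was 964. For lists, 29 of 100 relabellings gave at least the real 11, the highest other 14. Relabelled groups mix libraries of different treatments, which widens the spread within groups and lowers the counts of genes. The count of 964 therefore cannot exclude chance for the real count. Up to 9092 genes had an unadjusted p under 0.05 in edgeR with 14 lists called. The list counts thus carry part of the real differences and do not show how many lists chance alone gives. Splits of 6 libraries number 10, too few for a share under 0.05. The real counts of genes and the highest of other splits were 23132 and 2 for Cd against control, 21553 and 0 for Cd+OP against Cd, 18761 and 0 for control+OP against control, and 20229 and 0 for Cd+OP against control+OP, where up to 582, 647 and 616 genes had an unadjusted p under 0.05 in edgeR in the latter comparisons. The numbers of lists were 17 and 13, 13 and 11, 8 and 5, and 14 and 11, where other splits mix the 2 treatments as well.

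Of 28 nodulation genes 21 were higher in control+OP than in control and 6 lower, GLYMA_11G121800 among the latter (camera adjusted p = 0.00175, and 0.328 with an estimated correlation). A single mislabelled or swapped library is argued against, because over 30340 genes each of the 12 libraries correlated more with its own group than with any other library, by at least 0.046, while an exchange of whole groups would leave this value as it is and stays open. For nodule tissue, urate oxidase, an enzyme abundant in soybean nodules, was expected beforehand to be at least 2 higher on the log2 scale; the value was -0.22, so that prediction was not met. The explanation was left open for a reason set after that value was seen: the 1 annotated gene, GLYMA_20G072400 (outside the rule for named genes), stood at 46.0 FPKM in control and 39.4 in control+OP, and so high a baseline could hide a small share of nodule tissue. Low levels elsewhere do not come as a whole from carry-over, since over 18 members the level as a share of control+OP differed 22.72-fold (90th over 10th percentile) in control and 8.99-fold in Cd+OP. The highest shares were those of GLYMA_01G028500 and GLYMA_02G036800 (outside the rule for named genes), 30.1 and 33.6% in Cd+OP. The named nodulation genes that were higher in control+OP lay closer together, at 0.303 to 1.15% in control and 1.32 to 2.30% in Cd+OP. For these genes carry-over or traces of nodule tissue stay open. Whether rhizobia were present is not given in the sources used here.

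The Cd response was smaller with OP by its SD, 0.769 against 1.17. The slope of 0.25, and 0.1639 with no filter on low values, also reflects the low correlation of the responses. Noise in the Cd contrast without OP is argued against as the cause of the low slope by the slope corrected for it, 0.2549. A single library is argued against by the highest slope without 1 of the 12, 0.2529. A smaller uptake of Cd by the roots, a change in the medium and a direct effect of OP on the plant stay open and untested, and the Cd dose of each group could not be read from the labels. A batch shared by the libraries of a group cannot be seen in the labels.

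Gene lists for water channels, cell division and vascular tissue were lower with Cd. Gene length is argued against as the whole cause: 12 of 13 lists called lower kept the call after the length trend was removed (Spearman from 0.078 to 0.018), while class III peroxidases lost it, with the median going from -0.50 to -0.40 and camera adjusted p from 0.0449 to 0.146. A few genes taking most counts are argued against by a difference of 0.5 percentage points in the share of the top 10 genes. A smaller share of vascular cells would lower their genes alike, and the values go both ways: the xylem and phloem list, as broad as its terms, had an interquartile range of 3.61 with 17 of 92 higher, but 14 of 14 genes of phloem development fell (median -3.89, interquartile range 0.96, camera adjusted p = 2.68e-07, and 0.0614 with an estimated correlation). A loss of such cells and a change within cells may both contribute and stay open.

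Lists that camera called for the interaction with the preset correlation had median interaction values of 1.47 for aquaporins, 0.37 for cell division, 1.68 for endodermis and suberin, 0.27 for ethylene, -0.10 for heat shock, -0.37 for isoflavonoids, 0.73 for jasmonate, 0.54 for metal chelation, -3.34 for nodulation, 0.91 for seed storage and 1.18 for xylem and phloem. With an estimated correlation 4 of these 11 calls ended, for heat shock, metal chelation, nodulation and seed storage (camera adjusted p = 0.107, 0.079, 0.33 and 0.102). Below are the interaction values of named genes that edgeR called, 93 of 97, 55 higher and 38 lower, on the log2 scale.

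The named fatty acid binding genes had lower OP effects under Cd: GLYMA_11G225000 -4.74, GLYMA_18G033100 -4.43, GLYMA_18G032600 -4.71 and GLYMA_18G032400 -5.07. The protease inhibitor list did not pass (19 of 51 higher, 26 lower, camera adjusted p = 0.243), and of its named genes those lower were GLYMA_09G163200 -3.84, GLYMA_09G162800 -3.78, GLYMA_09G163800 -2.58, GLYMA_09G162500 -3.58, GLYMA_09G163000 -3.54, GLYMA_09G163300 -3.40 and GLYMA_16G212400 -0.26, while GLYMA_18G231400 5.50, GLYMA_16G212200 2.11 and GLYMA_08G341400 0.75 went the other way. The call for GLYMA_16G212400 ended with limma and a pseudocount of 0.1, without control library 3 (-0.18, adjusted p = 0.0522, edgeR) and without Cd library 2 (-0.16, adjusted p = 0.0616, edgeR). Abscisic acid binding genes GLYMA_09G040400 and GLYMA_15G145600 stood at -4.55 and -3.01, metal transport genes GLYMA_08G181900 and GLYMA_01G219000 at -1.58 and 0.65, and the autophagy gene GLYMA_17G084700 at -1.60. Named nodulation genes that were lower were GLYMA_20G024200 -7.37, GLYMA_15G045000 -6.60, GLYMA_13G364400 -6.60, GLYMA_08G120100 -5.73, GLYMA_14G052400 -6.59, LBA -7.29, LGB1 -5.05 and GLYMA_10G199000 -6.79, whereas GLYMA_11G121800 3.33 and SS 2.42 were higher.

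The named aquaporin genes had higher OP effects under Cd: GLYMA_05G208700 2.69, GLYMA_13G325900 2.18, GLYMA_11G228000 2.22, GLYMA_19G108400 1.54 and GLYMA_03G185900 0.56. Named cell division genes stood at 3.96 (GLYMA_02G277600), 2.61 (GLYMA_08G291000), 4.19 (GLYMA_14G037100), 1.17 (GLYMA_04G088500), 0.13 (GLYMA_17G255600) and 0.25 (GLYMA_10G163300), with GLYMA_06G088800 at 5.79, and 2 tubulin-type genes at -0.47 (GLYMA_04G023900) and -0.52 (GLYMA_06G024100). The call for GLYMA_17G255600 ended without Cd+OP library 2 (0.12, adjusted p = 0.0585, edgeR). Named vascular and barrier genes that were higher were GLYMA_02G000700 2.94, GLYMA_10G000500 2.54, GLYMA_10G185700 4.36, GLYMA_10G075500 5.07, GLYMA_10G075600 4.01, GLYMA_14G192500 2.41 and the laccase-type GLYMA_14G056100 1.31, whose call ended with limma on log2(FPKM + 1) (0.14, adjusted p = 0.291, limma). The named lipoxygenase and jasmonate genes LOX1.4 3.63, GLYMA_13G347700 3.61, GLYMA_07G034800 4.63 and GLYMA_14G078600 1.83, peroxidase genes GLYMA_05G103600 2.26 and GLYMA_03G208200 4.0, storage genes VSPB 2.93 and GLYMA_16G060800 1.99, pectinesterase genes GLYMA_01G137700 1.37 and GLYMA_03G029400 1.86, and GLYMA_19G046800 4.32 were higher too.

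Phenylpropanoid and isoflavonoid genes were split, with CYP73A11 -2.04, GLYMA_11G011500 -2.17 and GLYMA_11G054500 -1.39 lower and GLYMA_20G114200 0.83 and CYP93E1 2.35 higher. Chaperone genes GLYMA_03G171100 and GLYMA_12G064000 stood at -2.11 and -1.69, ribosomal protein genes GLYMA_10G223400 and GLYMA_14G061100 at 0.33 and -0.66, defense genes GLYMA_02G042500 and GLYMA_03G132700 at -2.19 and 1.02, and GLYMA_11G198500 at -0.30. Alcohol dehydrogenase GLYMA_04G213900 stood at 2.0 and the anoxia-annotated regulator GLYMA_19G213100 at 3.32. Transcription factor genes GLYMA_10G067000, GLYMA_03G002300 and GLYMA_02G008200 had 3.99, 3.67 and -0.94. Proteolysis genes GLYMA_10G180500 and GLYMA_15G260700 had 1.27 and -5.65. Further values were 4.85 (GLYMA_16G134600), 4.29 (GLYMA_02G069700), -3.93 (GLYMA_05G065700), 2.67 (GLYMA_06G192100), 3.64 (GLYMA_04G183100), -0.65 (GLYMA_11G158200), 2.09 (GLYMA_04G239900), -0.98 (GLYMA_10G201700), 5.62 (GLYMA_10G092800), 5.54 (GLYMA_01G131100), 5.25 (GLYMA_13G199500) and 2.27 (GLYMA_18G045200). GLYMA_02G028600 had 8.07, which rests on single libraries: without Cd+OP library 1 it was 1.25 (adjusted p = 0.769, edgeR) and without control library 1 it was 5.89 (adjusted p = 0.0513, edgeR). The interaction was not called by edgeR for GLYMA_01G202100, GLYMA_10G048600, GLYMA_06G324300 and GLYMA_13G293500.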

How the results depend on the processing

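Limma on log2(FPKM + 1) was the test first planned for FPKM values. It called 22944, 21209, 18551, 20303 and 18941 genes in the 5 comparisons. Its use as an alternative, DESeq2, counts divided by 4 and all alternatives for annotation terms were chosen only after the result was seen. With a mean of at least 5 FPKM, which leaves fewer genes to test, genes called were 13201 for Cd against control, 12874 for Cd+OP against Cd, 11494 for control+OP against control, 12241 for Cd+OP against control+OP and 11822 for the interaction. Lists for Cd against control were then 10, annotation terms 196 (Cd against control), 186 (Cd+OP against Cd), 119 (control+OP against control) and 202 (interaction), and genes moved back 9585. With a 2-fold minimum, a stricter threshold, the 5 counts of genes were 7570, 5990, 3781, 3733 and 7203. With an estimated correlation the lists were 8 for Cd against control, 1 for control+OP against control and 7 for the interaction, and the terms 0, 15, 0, 216 and 14, since this test allows for correlation within each set (434 and 362 terms had an unadjusted camera p under 0.05 where 0 passed). The slope of the Cd response with OP on that without was 0.1639 with no filter, where genes near 0 enter. Lists lost are named with their comparisons, and the cause was not tested.

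Without 1 library, genes called were 21970 to 23113, 20569 to 21562, 17135 to 18762, 19083 to 20359 and 18556 to 18876 in the 5 comparisons. Lists numbered 16 to 17, 13 to 14, 8 to 9, 14 to 15 and 11 to 12, and terms 305 to 336, 286 to 299, 209 to 230, 490 to 510 and 285 to 325. The slope was 0.2402 to 0.2529, and genes moved back 15401 to 16414. The named genes were chosen for large changes or small adjusted p in these same libraries, so most of their calls were likely to stay. The following counts are therefore no separate support. Of 4193 values of 200 named gene results under alternatives, 4178 kept direction and call, 15 lost the call and 0 reversed. Those that lost it were of GLYMA_02G028600 (whose values rest on single libraries) in control+OP against control and the interaction, and of the interaction of GLYMA_16G212400, GLYMA_14G056100 and GLYMA_17G255600.

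The share of calls that were higher in the 5 comparisons was 45.2 to 49.8%, 49.5 to 57.5%, 48.9 to 56.4%, 49.8 to 57.6% and 52.3 to 58% over the alternatives other than the 2-fold minimum. With the replicate number as a block the counts of genes were 23046, 21445, 18643, 20145 and 19309. Residuals of libraries with the same number correlated at -0.0218 to 0.0564 over 18 pairs, others at -0.0485 to 0.0249. For 8 of 12 libraries the best match in another group had the same number, so a weak pairing cannot be excluded. With 0 of 18 above 0.1, the numbers were not treated as pairs. No scaling moved the median log2 fold change by over 0.1. TMM and median of ratios scaling both take most genes as unchanged, so their agreement tests little where most genes were called. Smaller shifts also mattered for Cd+OP against Cd. With limma and a pseudocount of 0.1 its median went from 0.0011 to 0.0714, and its share of higher calls from 51.3 to 57.5%. On simulated data 31.2% of 1.2-fold changes were recovered, and the part of depth in this was not tested.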

Other observations

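The annotation terms below were singled out only after the result was seen, while the test of fermentation genes was written beforehand. Genes of mitochondrial respiratory chain complex I fell with Cd in 52 of 56 members (camera adjusted p = 9.73e-11) and rose in 48 in Cd+OP against Cd (camera adjusted p = 2.30e-09), and adjusted p = 0.0536 and 0.0534 with an estimated correlation. Genes of the sterol biosynthetic process fell with Cd in 32 of 38 members, rose in 32 in control+OP against control, and fell in 33 in Cd+OP against control+OP (camera adjusted p = 1.22e-06, 3.47e-06 and 7.51e-12), and adjusted p = 0.0614, 0.133 and 0.0134 with an estimated correlation. In Cd+OP against control+OP, 55 of 71 genes of the tricarboxylic acid cycle and 79 of 100 of the proteasome complex fell (camera adjusted p = 2.53e-10 and 9.65e-11), and adjusted p = 0.0186 and 0.0186 with an estimated correlation. Genes annotated with Golgi membrane fell in Cd+OP against Cd in 177 of 324 members (camera adjusted p = 8.01e-04), and adjusted p = 0.0357 with an estimated correlation. The broad heat shock list did not pass for Cd against control. The narrower term heat shock protein binding rose there in 33 of 42 members and fell in 4 (camera adjusted p = 1.17e-06). In Cd+OP against Cd 27 of its members fell and 7 rose (camera adjusted p = 3.10e-04). With an estimated correlation adjusted p was 0.116 and 0.201.

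Control roots may have had less oxygen than control+OP roots. Alcohol dehydrogenase gene GLYMA_04G213900 and the oxygen carrier GLYMA_11G121800 were lower in control+OP, and pyruvate decarboxylase genes, the other enzyme of ethanol fermentation, were then predicted to be lower as well. They fell in 5 of 5 members, with a median log2 change of -2.80, which met the prediction. With Cd 5 of 5 were lower than in control too, 4 of them at least 4-fold (log2 -2.37 to -3.47). The gene with the highest level, GLYMA_13G231700, singled out after its values were seen, stood at 486 FPKM in control, 43.9 with Cd, 69.7 in control+OP and 104 in Cd+OP. The exception among the 5, GLYMA_01G118000, changed by log2 -0.83 with Cd and stood at 37.2 FPKM in control, 4.81 in control+OP and 5.34 in Cd+OP. GLYMA_04G213900 also stayed nearer to control (259 FPKM) with Cd (147) than in control+OP (12.8) and Cd+OP (30.7). An effect of OP and a difference in growth conditions both stay open, and the growth conditions of each group are not given in the sources used here. A difference in the growth of the control roots would also enter the results for Cd against control and for genes moved back.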
